A study of Homo sapiens with 45 samples.

How the data were processed

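RNA was taken from 45 human renal cell carcinoma samples, and libraries were prepared with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes list Trimmomatic, STAR, RSEM and the genome build hg19, without versions or the order of use; the gene annotation is not given in the sources used here. The authors deposited 1 table of RSEM expected counts for 17849 gene symbols, which are estimated read counts that share ambiguous reads between genes and are not scaled between samples. Values with no decimal part, counted with no tolerance, made up 79.2% of the table. Members of near-identical gene families, such as histones and ribosomal proteins, depend on how RSEM shared their reads, and are uncertain for that reason.

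Samples were grouped by the class in their titles, giving 24 sarcomatoid-high and 20 sarcomatoid-low tumours. The 1 sample whose title named both classes was kept out of all comparisons. Replicate numbers formed a single series over both classes and the labels name no donors, so any pairing is unknown and none was fitted. The closest pair of libraries had a chi-square of 80.4 per gene against 1 expected from counting noise, so no library was treated as a repeat sequencing of another. This does not show that close libraries come from separate tumours or patients, and 3 same-class pairs had a Spearman correlation over 0.94. The 71 genes that follow donor sex (Y-linked genes, XIST and TSIX) were left out of every fit and carried 0.182% of all counts. The table held 0 mitochondrially encoded genes.

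Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which removed 3795 and left 13983. TMM normalization, estimateDisp, glmQLFit and glmQLFTest were run without robust estimation, with the class as the only term. Tests were two-sided, with Benjamini-Hochberg adjustment and a limit of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Levels are TMM-scaled CPM, and library totals are given in M (mega) counts. A fitted log2 fold change compares class means, so a few tumours with high counts weigh heavily on it.

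Before the data were examined, 33 gene lists were fixed. Of these, 30 with at least 5 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. The skeletal muscle and erythroid lists had too few tested members, and none of the 13 members of the mitochondrially encoded list was in the table. Per tumour, a list score was the mean log2 CPM of the members with a prior count of 2. Scores, components, depth and composition were compared with permutation tests of 100000 resamples. The variance explained by class was a PERMANOVA on Euclidean distances over the 2000 most variable genes.

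Genes named in the text followed a rule fixed beforehand. It took the 10 largest changes per direction among genes past the threshold, of which there were none, and the 5 smallest p in each direction. It also took up to 4 called members of each list, or 2 with the smallest p where none was called, and 18 genes whatever their result. Of the genes this rule takes, 2 were not used here.

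The edgeR steps were tested on simulated counts for 13983 genes with the real means, library sizes and dispersions. Of the 176 calls made, 7 were unchanged genes. On the real counts, 57 of 79 other splits of the tumours into 24 and 20 called at least 1 gene, with a median of 5 and up to 264. Depth was similar across tumours except for 1 library of 5.24 M counts, so transcripts near 1 CPM rest on few reads there.

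Alternatives covered RLE, upper quartile and library-size scaling, other count filters, DESeq2 1.42.0, robust edgeR, limma voom with and without quality weights, a Wilcoxon test, surrogate variables from sva 3.50.0 (5 fitted), covariates for nephron, stromal and leukocyte scores, and each library left out in turn. Transcript lengths came from GENCODE release 29, used only for a length check, in which 99.1% of tested genes had a length. Coordinates are not given because the reference at hand is of another build. Python 3.11.15 and numpy 2.4.6 were used for the permutation tests.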

Results

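Gene expression was measured by RNA sequencing in 45 renal cell carcinoma samples from human kidney. Sarcomatoid change is a spindle-celled, mesenchymal-looking growth pattern that can arise in any subtype of renal cell carcinoma. The labels placed 24 tumours in a sarcomatoid-high class and 20 in a sarcomatoid-low class, and the title of 1 further tumour named both classes, so it entered no comparison. The series asked which transcripts differ between the classes. Total counts ran from 5.24 to 20.63 M per library in the 44 compared tumours, with a median of 15.56 M. Sarcomatoid-high libraries held 15.6 ± 2.72 M counts (SD, n = 24) and sarcomatoid-low libraries 15.7 ± 3.45 M (SD, n = 20; two-sided permutation p = 0.897). Genes with at least 10 counts numbered 13598 ± 256 (SD, n = 24) and 13555 ± 315 (SD, n = 20; permutation p = 0.621). The 10 largest genes of a library took 5.79% ± 1.25 of its counts in sarcomatoid-high and 5.54% ± 1.58 in sarcomatoid-low tumours (permutation p = 0.562). The labels name no donors, batches or tumour subtypes, so the p-values of genes, scores and components below measure the spread between these samples. Those from camera at the preset correlation compare list members with the other genes and do not measure that spread.

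The classes overlapped almost entirely in their overall expression profile. The sarcomatoid class accounted for 2.02% of the variance of the 2000 most variable genes, against a mean of 2.32% when class labels were permuted (permutation p = 0.607). Principal component 1 held 18.6% of the variance, and its scores were -7.91 ± 44.3 in sarcomatoid-high tumours (SD, n = 24) and 9.50 ± 38.1 in sarcomatoid-low tumours (SD, n = 20; permutation p = 0.173). Component 2 held 12.9% (permutation p = 0.838) and component 3 held 7.61% (permutation p = 0.920). Sarcomatoid-high tumours lay 95.7 ± 15.4 units from their class centroid and sarcomatoid-low tumours 92.0 ± 16.6 units (permutation p = 0.453).

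**Figure D1:**
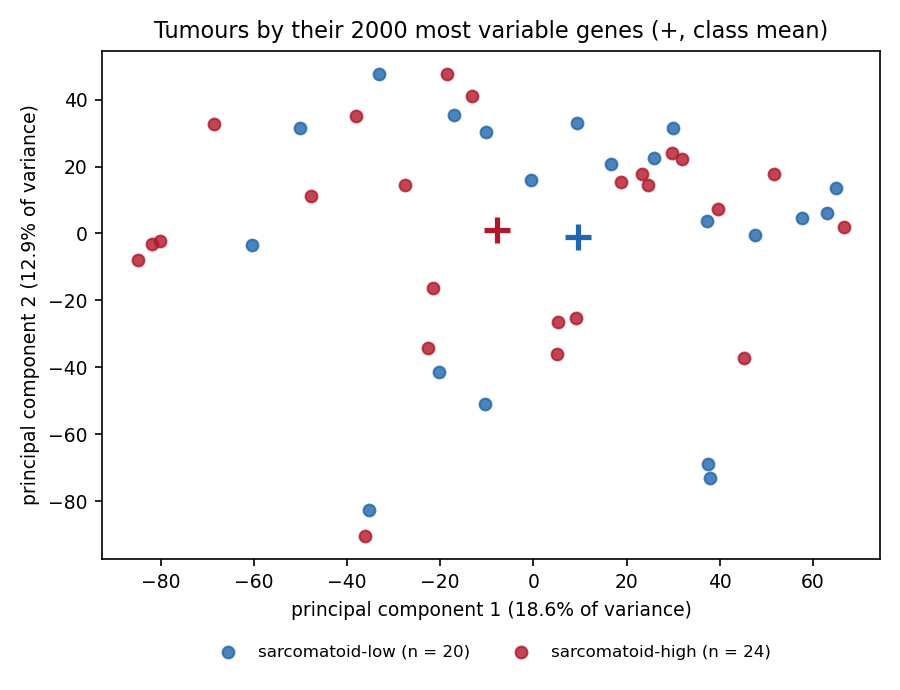
Scores of the 44 tumours on principal components 1 and 2 (arbitrary units of log2 CPM), coloured by sarcomatoid class, with a cross at each class mean. The classes overlap on both components, which hold 18.6% and 12.9% of the variance.

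No single gene separated the classes after adjustment for multiple testing. Of 13983 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 were lower in sarcomatoid-high tumours at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 918 genes, 6.57% of those tested, of which 650 had the higher mean in sarcomatoid-high and 268 in sarcomatoid-low tumours. That balance depended on the method, at 231 and 209 with limma voom, 271 and 172 with the Wilcoxon test, and 289 and 352 with surrogate variables as covariates. DESeq2 called 17 genes higher and 3 lower (PPP1R3B and, named after their values were seen, C8orf34 and CHL1), and limma voom, voom with quality weights and the Wilcoxon test each called 0. With no filter on low counts edgeR called 89 higher and 44 lower, of which 112 were genes that the filter removes. These calls included DES (adjusted p = 0.0297) and all 9 genes named below for their small p, from SOSTDC1 (0.00641) and RSPO3 (0.0117) to GNG4 (0.0453). The biological coefficient of variation between tumours was 0.758. Counts were also simulated for 13983 genes with dispersions fitted gene by gene. There the same test recovered 48% of 50 genes changed 2-fold, 86% of 50 changed 4-fold and 98% of 50 changed 8-fold. The simulation drew genes independently of each other, unlike the real counts, so these shares do not show what the real comparison could find.

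Toward sarcomatoid-high, the gene with the smallest p was RSPO3, a secreted amplifier of WNT signalling. It averaged 17.01 ± 33.02 CPM in sarcomatoid-high (SD, n = 24) and 1.41 ± 1.33 CPM in sarcomatoid-low tumours (SD, n = 20), with medians of 1.92 and 1.17 CPM. Its log2 fold change was 3.58 ± 0.73 (SE) with edgeR's adjusted p = 0.0866, and DESeq2 called it with an adjusted p of 1.46e-05. WNT5B, a non-canonical WNT ligand, had a log2 fold change of 3.04 ± 0.68 (edgeR adjusted p = 0.119). OXTR, the oxytocin receptor, averaged 17.6 ± 30.5 against 4.04 ± 2.73 CPM, and its log2 fold change of 2.12 ± 0.47 had an adjusted p of 0.119 in edgeR and 0.00293 in DESeq2. KIAA1755 had a log2 fold change of 3.71 ± 0.82 (edgeR adjusted p = 0.119), with medians of 3.14 and 1.62 CPM, and 1 library, sarcomatoid-high 44, held 81.4% of the sarcomatoid-high sum. DESeq2 did not call WNT5B or KIAA1755. In 7 of the 9 genes named here for their small p, 4 toward sarcomatoid-high and 5 toward sarcomatoid-low, the 2 highest libraries of the class with the higher mean held over 50% of that class's summed CPM.

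Toward sarcomatoid-low, the smallest p belonged to SOSTDC1, a secreted antagonist of BMP and WNT signalling. It averaged 2.31 ± 2.65 CPM in sarcomatoid-high (SD, n = 24) and 106 ± 367 CPM in sarcomatoid-low tumours (SD, n = 20), while the medians were 0.833 and 1.196 CPM. The sarcomatoid-low mean was set by libraries 45 (1592 CPM) and 39 (502 CPM), which held 98.7% of the class sum and had similar profiles (Spearman rho = 0.942 across genes). Its log2 fold change was -5.51 ± 1.05 (SE, edgeR adjusted p = 0.0521), and the sign turned with DESeq2 (0.64, adjusted p = 0.819). In 22 of 44 fits that left out 1 library, its edgeR adjusted p was between 0.0224 and 0.0488. PPP1R3B, a glycogen-targeting subunit of protein phosphatase 1, averaged 152 ± 80.3 CPM against 322 ± 260 CPM, with medians of 127 and 264 CPM. Its log2 fold change of -1.08 ± 0.26 had an adjusted p of 0.183 in edgeR and 0.0339 in DESeq2. SLC9A3, the sodium-proton exchanger NHE3 of the proximal tubule, had a log2 fold change of -3.35 ± 0.72 (edgeR adjusted p = 0.119). PCDH20 (-3.81 ± 0.97) and GNG4 (-3.50 ± 0.89) both had an edgeR adjusted p of 0.224. DESeq2 did not call SLC9A3, PCDH20 or GNG4. PCDH20 changed sign with voom quality weights (0.30), and the median CPM of GNG4 was the higher in sarcomatoid-high tumours (0.589 against 0.347). A single library held 57.3% of the summed CPM of the class with the higher mean for WNT5B, 75.1% for SOSTDC1, 85.3% for PCDH20 and 79.4% for GNG4.

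**Figure D2:**
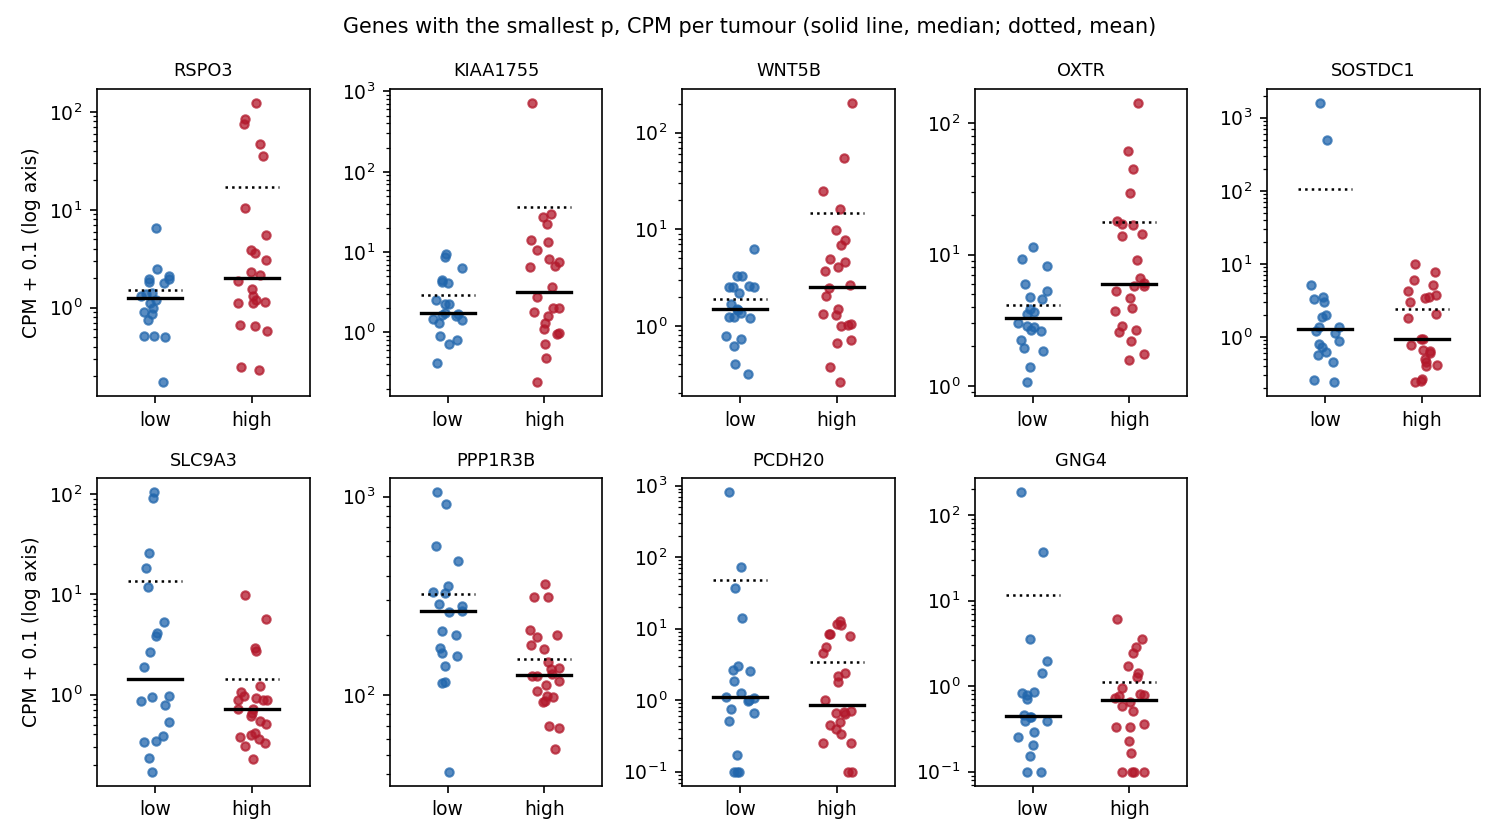
CPM per tumour (plus 0.1, log axis) of 9 of the genes with the smallest p, by sarcomatoid class; each point is 1 tumour, the solid line is the median and the dotted line the mean. Most of the means are set by a few tumours, as for SOSTDC1 (medians 0.833 and 1.196 CPM). Among the genes that also differ in their medians are PPP1R3B (127 and 264 CPM), OXTR (5.86 and 3.18 CPM), KIAA1755 (3.14 and 1.62 CPM) and SLC9A3 (0.613 and 1.32 CPM).

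Gene lists for cell division, histones, ribosomes, stroma, the mesenchymal state and macrophages lay toward sarcomatoid-high, and epithelial, hypoxia, papillary-associated and immediate early lists toward sarcomatoid-low. These calls rest on the correlation between genes that the test assumes. Of 30 lists tested with camera at a preset correlation of 0.01, 7 were higher and 4 lower in sarcomatoid-high tumours at an adjusted p under 0.05. The estimated correlation of the called lists ran from 0.276 (papillary) to 0.825 (proliferation), and was 0.660 for histones and 0.671 for ribosomal proteins. These values lie far above the preset 0.01, so the p-values at the preset correlation are too small for these lists. With an estimated correlation 0 lists were called, the smallest adjusted p being 0.663, and the fry test and the permutation test of the mean list score also called 0. Among 80 splits of the 44 tumours into 24 and 20, the real one included, 45 gave at least 11 called lists. Leaving out the library with 5.24 M counts kept the list counts at 7 and 4, and gave 0 genes higher and 1 lower (SOSTDC1, edgeR adjusted p = 0.0419). For lists, that check, the length slope and proliferation score as covariates, the closest library pairs and each library left out were added after the data were seen. No member of any list passed edgeR's adjustment over all genes, and the count adjusted over the list alone was 0 for each list where none is given.

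Cell cycle genes leaned toward sarcomatoid-high, and were called as a list with the preset correlation only. In the proliferation list, 28 of 29 members had a log2 fold change above 0 and the median was 0.67, with 0 members past the threshold when adjusted over the list alone. The list had an adjusted p = 1.42e-08, and adjusted p = 0.786 with an estimated correlation. Its score was 4.21 ± 1.39 log2 CPM (SD, n = 24) against 3.74 ± 1.10 (SD, n = 20; permutation p = 0.225), and 14 of 24 sarcomatoid-high tumours lay above the sarcomatoid-low median. FOXM1, a transcription factor of the G2 and mitotic genes, averaged 53.1 ± 89.1 against 21.2 ± 20.2 CPM, a log2 fold change of 1.32 ± 0.45 (edgeR adjusted p = 0.594). CENPF, a kinetochore protein, had a log2 fold change of 1.09 ± 0.42 (edgeR adjusted p = 0.639). The proliferation marker MKI67 averaged 384 ± 507 and 208 ± 304 CPM (log2 fold change 0.88 ± 0.49), and topoisomerase TOP2A 105 ± 114 and 61.7 ± 65.3 CPM (0.77 ± 0.45). The list's median was 0.21 with nephron list scores as covariates and 1.01 without sarcomatoid-low 55.

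Replication-dependent histone transcripts gave the smallest list p. All 16 members had a log2 fold change above 0, with a median of 0.67, and 14 of 24 sarcomatoid-high tumours scored above the sarcomatoid-low median. The list had an adjusted p = 8.17e-12, and adjusted p = 0.663 with an estimated correlation. When adjusted over the list alone 5 members were higher: HIST1H1B, HIST1H1D and, named after their values were seen, HIST1H2BK, HIST1H4H and HIST2H3D. The score was 5.11 ± 0.953 log2 CPM in sarcomatoid-high (SD, n = 24) and 4.56 ± 0.688 in sarcomatoid-low tumours (SD, n = 20), with a permutation p of 0.0385 that became 0.876 over the 30 lists. The linker histone HIST1H1B averaged 79.7 ± 110 against 26.8 ± 17.9 CPM (log2 fold change 1.57 ± 0.46, edgeR adjusted p = 0.401). Another linker histone, HIST1H1D, averaged 39.9 ± 43.9 against 18.7 ± 15.1 CPM. The histone median was 0.37 with nephron list scores and 0.22 with the proliferation score as covariates. These transcripts mostly lack poly(A) tails, and the kit named in the labels selects mRNA. Cytosolic ribosomal proteins differed less, with 34 of 36 members above 0, a median log2 fold change of 0.31 and an adjusted p of 5.83e-11 (adjusted p = 0.786 with an estimated correlation), and 14 of 24 tumours above the sarcomatoid-low median. Their median was 0.17 with each library's length slope as a covariate. RPL32 averaged 122 ± 60.7 and 87.6 ± 30.2 CPM, and RPL3 354 ± 168 and 261 ± 80.9 CPM. MYC targets and ribosome biogenesis genes were not called (adjusted p = 0.186), and within them UTP20 had a log2 fold change of -0.34 ± 0.14 and NCL one of 0.37 ± 0.20.

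Stromal lists lay toward sarcomatoid-high. In the list of fibroblast, pericyte and smooth muscle markers, 16 of 17 members had a log2 fold change above 0, with a median of 0.72 (adjusted p = 0.000675, and adjusted p = 0.786 with an estimated correlation). The scores of 15 of 24 sarcomatoid-high tumours lay above the sarcomatoid-low median, as they did for collagen. DES, the muscle intermediate filament desmin, averaged 25.9 ± 77.01 against 0.976 ± 1.80 CPM, with medians of 0.651 and 0.229 CPM. It was the only member higher when adjusted over the list alone (log2 fold change 4.72 ± 1.13, edgeR adjusted p = 0.183 over all genes). The smooth muscle protein CNN1 had a log2 fold change of 1.42 ± 0.55, but its median was the lower in sarcomatoid-high tumours (2.84 against 3.78 CPM). In the fibrillar collagen and matrix list, 15 of 20 members lay above 0 with a median of 0.33 (adjusted p = 0.000675, and adjusted p = 0.786 with an estimated correlation). COL5A2 averaged 285 ± 518 against 126 ± 207 CPM. COL11A1 had the lower mean in sarcomatoid-high tumours, with 12.2 ± 15.6 against 35.6 ± 77.4 CPM, but the higher median (8.26 against 3.35 CPM). COL1A1 averaged 1388 ± 1759 and 1084 ± 2446 CPM (log2 fold change 0.36 ± 0.65), with medians of 761 and 182 CPM. The collagen list's median was 0.20 without sarcomatoid-high 58, 0.65 without sarcomatoid-low 37 and 0.89 without sarcomatoid-low 51, and it was 0.53 with the length slope and 0.15 with the proliferation score as covariates. The fibroblast list's median was 0.48 without sarcomatoid-high 64.

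The mesenchymal and EMT list had 19 of 22 members above 0 and a median log2 fold change of 0.25. It had an adjusted p = 0.00159, and adjusted p = 0.786 with an estimated correlation. Its score was 6.73 ± 0.994 against 6.28 ± 1.2005 log2 CPM (permutation p = 0.184), and 18 of 24 sarcomatoid-high tumours lay above the sarcomatoid-low median. Fibronectin, FN1, averaged 6100 ± 8482 against 2129 ± 3017 CPM, a log2 fold change of 1.52 ± 0.51 (edgeR adjusted p = 0.593). WNT5A averaged 123 ± 175 against 62.7 ± 88.8 CPM. Vimentin, VIM, averaged 2323 ± 1313 and 2048 ± 1194 CPM (log2 fold change 0.18 ± 0.29, -0.02 with voom quality weights). N-cadherin, CDH2, averaged 152 ± 117 and 131 ± 86.3 CPM, and E-cadherin, CDH1, 168 ± 175 and 176 ± 197 CPM. Epithelial junction and keratin genes lay lower, with 6 of 22 members above 0 and a median of -0.32 (adjusted p = 0.0140, and adjusted p = 0.874 with an estimated correlation). The tight junction gene CLDN7 averaged 26.7 ± 31.3 against 52.02 ± 57.4 CPM and the mucin MUC1 51.8 ± 52.9 against 81.8 ± 67.7 CPM. With fibroblast and macrophage list scores as covariates, the mesenchymal, collagen and epithelial lists each had an adjusted p of 0.817 and their medians turned to -0.03, -0.17 and 0.15. With the proliferation score as a covariate the mesenchymal (adjusted p = 0.0883, median 0.13) and epithelial (adjusted p = 0.377, median -0.20) calls were lost, and the epithelial call was also lost without 1 library of each closest pair (adjusted p = 0.299, median -0.10). The mesenchymal median was 0.17 without sarcomatoid-high 58 and 0.57 without sarcomatoid-low 51, and the epithelial median was 0.0013 without sarcomatoid-low 41 and -0.10 without sarcomatoid-low 45. TGF-beta response genes (adjusted p = 0.483) and YAP and TAZ targets (adjusted p = 0.863) were not called. In these, LTBP2 had a log2 fold change of 1.19 ± 0.52, TGIF1 one of -0.44 ± 0.18, AMOTL1 one of 0.57 ± 0.30 and NT5E one of 0.96 ± 0.52.

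**Figure D3:**
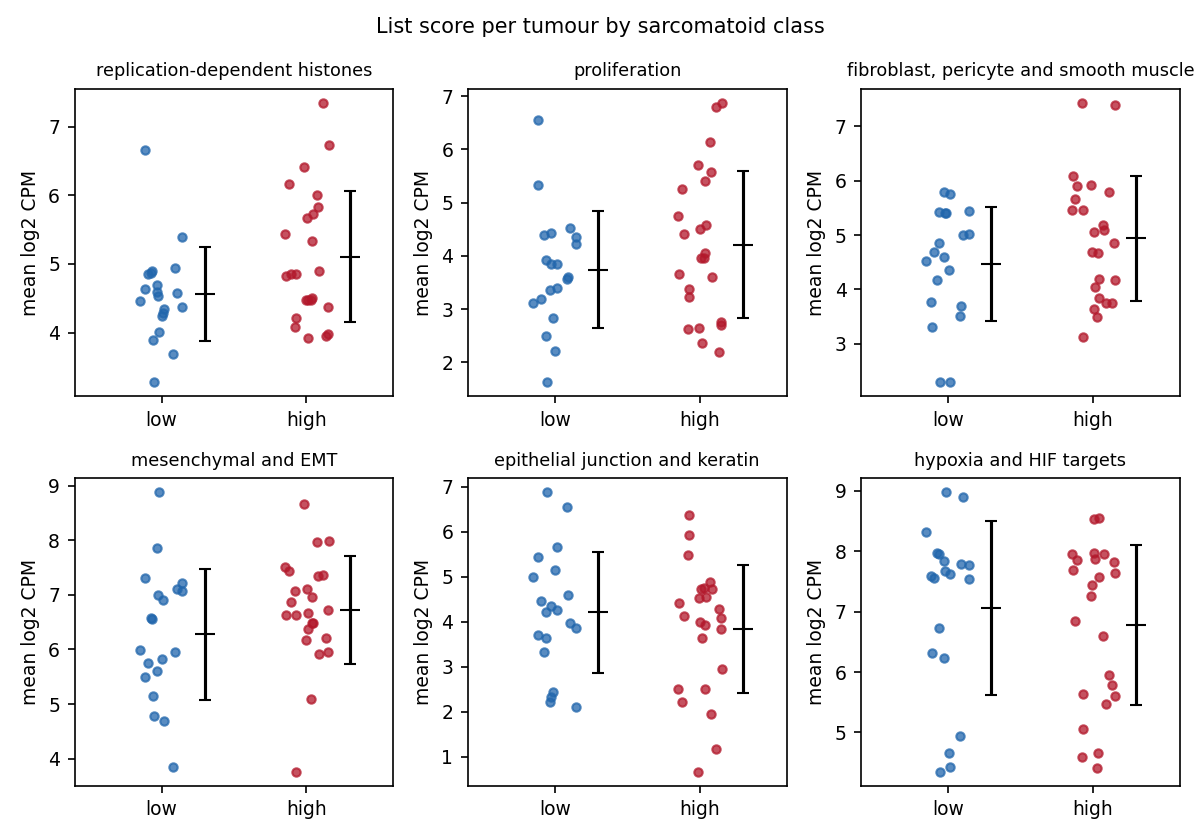
Mean log2 CPM of 6 gene lists in each tumour by sarcomatoid class; each point is 1 tumour, and the bar beside the points is the mean ± SD (n = 20 low, n = 24 high). The spread within each class exceeds the difference between class means, which for the histone list are 4.56 and 5.11.

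Hypoxia and HIF targets, the genes induced after loss of VHL in clear cell tumours, lay lower in sarcomatoid-high tumours as a list. Of 20 members 7 were above 0, and the median log2 fold change was -0.34 (adjusted p = 0.0234, and adjusted p = 0.878 with an estimated correlation). Leaving out any of 14 of the 44 libraries ended this call, and the median was -0.20 without sarcomatoid-low 51. VEGFA averaged 1261 ± 1309 against 2093 ± 2133 CPM, a log2 fold change of -0.73 ± 0.50 (edgeR adjusted p = 0.883). The glycolytic regulator PFKFB3 averaged 283 ± 151 against 457 ± 375 CPM. Carbonic anhydrase CA9 averaged 101 ± 115 and 99.2 ± 96.5 CPM, with a log2 fold change of 0.02 ± 0.73 that was -1.37 with voom quality weights. Endothelial and angiogenesis genes were not called (adjusted p = 0.483, median -0.10), but were called lower with fibroblast and macrophage scores as covariates (9.24e-06, median -0.32) and without 1 library of each closest pair (0.0188, median -0.23), settings not tested with an estimated correlation (adjusted p = 0.978 with all tumours and no covariate). With 1 library left out, the endothelial median ran from -0.23 to -0.025, and 1 of 44 fits called the list lower (adjusted p = 0.0263). The VEGF receptor KDR averaged 91.7 ± 124 and 95.8 ± 80.5 CPM. CLDN5 and ANGPT2 had log2 fold changes of 0.52 ± 0.34 and -0.45 ± 0.36. Immediate early and heat shock genes lay lower, with 4 of 22 members above 0 and a median of -0.35 (adjusted p = 0.00831, and adjusted p = 0.786 with an estimated correlation). EGR2 averaged 13.4 ± 21.2 against 34.1 ± 73.5 CPM and JUNB 163 ± 99.7 against 272 ± 334 CPM. Their medians were close, at 7.40 and 7.88 CPM for EGR2 and 146 and 151 CPM for JUNB. The list's median was -0.19 without sarcomatoid-low 51, where the call was lost, and -0.52 without sarcomatoid-high 54.

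Metabolic and nephron lists were not called when no covariate was fitted and all 44 tumours were kept. The proximal tubule list had an adjusted p of 0.0843, fatty acid oxidation and peroxisome 0.1498, oxidative phosphorylation 0.863 and the distal nephron, collecting duct and glomerulus list 0.997. With fibroblast and macrophage scores as covariates, oxidative phosphorylation was called higher (adjusted p = 2.08e-05) and its median turned from -0.06 to 0.16, a setting not tested with an estimated correlation. With 1 library left out, the proximal tubule list was called lower in 14 of 44 fits and fatty acid oxidation in 7. Oxidative phosphorylation was called higher in 1 such fit, and its median ran from -0.14 to 0.14. SLC13A3, a dicarboxylate transporter, averaged 44.02 ± 137 against 10.1 ± 18.2 CPM, and ACADL 23.5 ± 31.4 against 57.6 ± 62.1 CPM. FBP1 had a log2 fold change of -0.54 ± 0.36, SLC25A20 one of 0.30 ± 0.16, CYCS one of -0.53 ± 0.29 and COX6C one of -0.38 ± 0.22. SLC12A3 (1.61 ± 0.68) changed sign with DESeq2 and with voom quality weights, and AQP3 (0.87 ± 0.53) with voom quality weights. Papillary-associated genes were called lower with the preset correlation, with 3 of 11 members above 0 and a median of -0.29 (adjusted p = 0.0279, and adjusted p = 0.786 with an estimated correlation). LRRK2 averaged 331 ± 307 against 634 ± 591 CPM and CD24 108 ± 96.8 against 170 ± 102 CPM. The papillary call was lost with fibroblast and macrophage scores (adjusted p = 0.449, median turned to 0.10), the length slope (adjusted p = 0.0857, median -0.09) or the proliferation score (adjusted p = 0.377, median 0.03) as covariates, and without 1 library of each closest pair (adjusted p = 0.477, median 0.06). Its median was -0.17 with nephron list scores as covariates, -0.14 without sarcomatoid-low 39 and -0.06 without sarcomatoid-low 45. The chromophobe and oncocytic list was not called (adjusted p = 0.759), and 1 tumour in each class stood far above the rest, at 10.2 and 10.1 log2 CPM. These 2 libraries decided its values: the list's median was -4.53 without sarcomatoid-high 25 and 3.52 without sarcomatoid-low 41. Its members CLNK and ATP6V0A4 had log2 fold changes of -0.46 ± 1.05 and -0.48 ± 1.23, the latter changing sign with DESeq2 and with voom quality weights. CLNK was called lower without sarcomatoid-high 25 (log2 fold change -4.53, adjusted p = 0.0322).

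Among the immune lists only macrophages and monocytes were called with the preset correlation. Their markers lay higher in sarcomatoid-high tumours, with 19 of 22 members above 0 and a median of 0.21 (adjusted p = 0.0103, and adjusted p = 0.878 with an estimated correlation), and 17 of 24 tumours above the sarcomatoid-low median. That count of tumours was also 17 for the TGF-beta response list and 16 for the neutrophil list, which were not called. For the lists called lower it was 11 (epithelial), 11 (papillary), 10 (hypoxia) and 7 (immediate early). The mannose receptor MRC1 averaged 87.8 ± 102 against 44.4 ± 40.8 CPM and the scavenger receptor CD163 470 ± 325 against 292 ± 223 CPM. The macrophage call was lost with the length slope (adjusted p = 0.0857, median 0.08) and the proliferation score (adjusted p = 0.0507, median 0.07) as covariates. Its median was 0.12 with nephron list scores as covariates, 0.09 without sarcomatoid-high 21, 0.10 without sarcomatoid-high 31 and 0.42 without sarcomatoid-low 49. The call was lost without sarcomatoid-high 21 (adjusted p = 0.0784) or 53 (0.0529) or sarcomatoid-low 41 (0.121) or 45 (0.118). Lists of cytotoxic T and NK cells (median -0.32, adjusted p = 0.358), checkpoints and regulatory T cells (median -0.56, adjusted p = 0.162), interferon response (0.863), neutrophils and inflammatory cytokines (0.863), B and plasma cells (0.759) and complement (0.670) were not called. With 1 library left out, the T and NK cell median ran from -0.53 to -0.14 and the checkpoint median from -0.72 to -0.18, with lower calls in 3 and 8 of 44 fits. With fibroblast and macrophage scores as covariates, the T and NK cell (adjusted p = 1.05e-06, median -0.73), checkpoint (3.68e-05, median -0.69), interferon (0.00534) and complement (0.0433) lists were called lower. The proliferation score as a covariate also gave lower calls for T and NK cells (0.0123, median -0.56), checkpoints (0.000846) and interferon (0.0344), and leaving out 1 library of each closest pair gave one for checkpoints (0.0197). With an estimated correlation and no covariate these 4 lists had an adjusted p of 0.978, and the calls with covariates or fewer libraries were not tested that way. When adjusted over the list alone, ISG15 was higher (log2 fold change 1.63 ± 0.49), as were CXCR2 (1.52 ± 0.47) and S100A9 (1.19 ± 0.41), the last named after its value was seen. IL6 was lower on the same adjustment (-2.61 ± 0.71) and changed sign with voom quality weights (0.36). Its median was the higher in sarcomatoid-high tumours (2.135 against 1.886 CPM). The T cell gene CD8A averaged 16.5 ± 19.3 and 22.99 ± 26.2 CPM. CD274, which encodes PD-L1, averaged 24.1 ± 33.8 and 15.3 ± 7.98 CPM, with a log2 fold change of 0.65 ± 0.40 that was -0.01 with voom quality weights. GZMB had a log2 fold change of 1.10 ± 0.52, CD3G one of -0.80 ± 0.48, BTLA one of -1.08 ± 0.50, TOX one of -1.10 ± 0.56 and IFI6 one of 1.30 ± 0.44. The median of GZMB was the lower in sarcomatoid-high tumours (2.18 against 2.69 CPM). BANK1 and MS4A1 had log2 fold changes of -1.05 ± 0.37 and -1.91 ± 0.76, and CFD and C7 had 1.27 ± 0.40 and 1.35 ± 0.84.

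Genes recurrently mutated in renal cancer showed small differences in transcript level. As a list they were not called (adjusted p = 0.863). PBRM1, a SWI/SNF subunit, averaged 168 ± 77.6 and 145 ± 44.8 CPM (log2 fold change 0.22 ± 0.18), and the deubiquitinase BAP1 had a log2 fold change of 0.30 ± 0.21. SETD2 averaged 206 ± 67.3 and 191 ± 73.3 CPM, VHL 60.5 ± 23.9 and 54.2 ± 15.2 CPM, and NF2 71.1 ± 50.98 and 64.8 ± 52.6 CPM. CDKN2A averaged 9.03 ± 18.1 and 10.7 ± 15.1 CPM, with medians of 3.47 and 7.27 CPM.

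Of the markers of other tissues, adipocyte (adjusted p = 0.118), hepatocyte (0.863) and lung epithelium genes (0.483) were not called. The adipocyte list was called higher with no filter on low counts (adjusted p = 0.0263), with the length slope (0.0278) or the proliferation score (0.00278) as a covariate, and without sarcomatoid-high 31 or 33 or sarcomatoid-low 57. Its adjusted p was 0.786 with an estimated correlation and the usual filter. With no filter, skeletal muscle genes were also called higher and erythroid genes lower (adjusted p = 0.0371 for both), and no call of this paragraph was tested with an estimated correlation under its own setting. FABP4, a fatty acid binding protein of fat cells, was higher when adjusted over the list alone (log2 fold change 2.94 ± 0.86) at 7.54 ± 21.1 against 0.975 ± 1.83 CPM. PLIN1 had a log2 fold change of 1.22 ± 0.53, AMBP one of 1.88 ± 0.70, ALB one of 1.42 ± 0.72, NAPSA one of -0.93 ± 0.65 and SFTPD one of -0.26 ± 0.45. The medians of PLIN1 (0.8785 against 0.8863 CPM) and ALB (0.5735 against 0.7068 CPM) were the lower in sarcomatoid-high tumours. The sign of the test and of the median differed for the oxidative phosphorylation, neutrophil, B and plasma cell, complement and hepatocyte lists. The median and the mean score differed in sign for the distal nephron, oxidative phosphorylation, interferon, neutrophil, B and plasma cell, complement, hepatocyte and renal cancer gene lists.

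**Figure D4:**
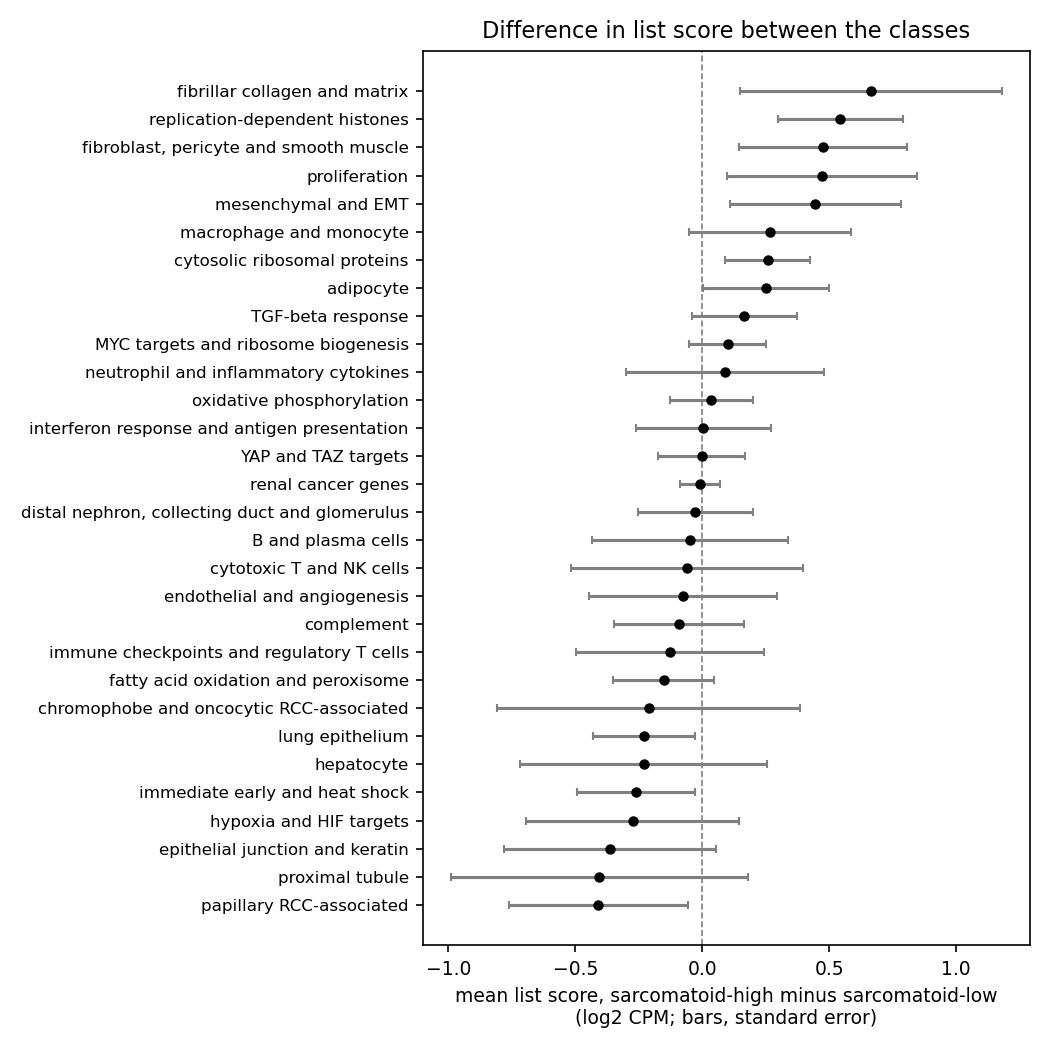
Mean list score in sarcomatoid-high minus sarcomatoid-low tumours (log2 CPM) for the 30 tested lists; bars are the standard error of the difference. The largest difference, 0.665 for fibrillar collagen and matrix, has a standard error of 0.517, and 0 lists passed an adjusted permutation p of 0.05.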

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

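Covariates for length slope and proliferation, the closest-pair check and the left-out libraries for lists were chosen after the data were seen. The edgeR counts of 0 genes higher and 0 lower (0 and 0 at least 2-fold) held under RLE, upper quartile and library-size scaling, robust estimation, voom with and without quality weights, the Wilcoxon test, surrogate variables, nephron covariates, an adjusted p limit of 0.01, the length slope and without 1 library of each closest pair. With no filter there were 89 higher and 44 lower (88 and 44 at least 2-fold). DESeq2 gave 17 higher and 3 lower (16 and 3 at least 2-fold). The stricter filter gave 0 higher and 1 lower (SOSTDC1, adjusted p = 0.0486), as did leaving out the shallow sarcomatoid-low library 26 (adjusted p = 0.0419). Fibroblast and macrophage covariates gave 2 higher and 1 lower (1 and 1 at least 2-fold): POLR2L, TALDO1 and SLC9A3. Leaving out 1 library gave 0 to 1 genes higher and 0 to 4 lower, the same ranges at least 2-fold; SOSTDC1 was called without any 1 of the sarcomatoid-low libraries except 39 and 45, and without sarcomatoid-high 25, 33, 35 or 36 (adjusted p 0.0224 to 0.0488). RSPO3 was called without sarcomatoid-low 20 or sarcomatoid-high 33 or 36 (0.0359 to 0.0488). Without sarcomatoid-high 25, ATP6V0D2, CLNK and SLC26A7 were also called, and without sarcomatoid-high 35 SLC9A3 was (0.0224). Without sarcomatoid-low 55, 1072 genes were higher unadjusted, and without sarcomatoid-high 25, 462 genes were lower unadjusted. Beyond the genes that the filters add or remove, the cause was not tested.

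Lists called with the preset correlation numbered 7 higher and 4 lower under RLE and library-size scaling, nephron covariates and without the shallow library or 1 of each closest pair, which exchanged the epithelial and papillary calls for endothelial (0.0188) and checkpoint (0.0197) calls. They numbered 9 and 5 with no filter, 7 and 3 with the length slope, and 5 and 5 with the proliferation score, which added T cell, checkpoint and interferon calls lower and adipocyte higher. Fibroblast and macrophage covariates gave 4 and 7, with the T cell, checkpoint, endothelial, interferon and complement lists lower and oxidative phosphorylation higher, and no call for the mesenchymal, collagen, epithelial or papillary lists (the last at 0.449). An estimated correlation gave 0 and 0, fry 0 and 0, and the permutation test 0 and 0. Leaving out 1 library gave 6 to 8 higher and 1 to 7 lower: 1 without sarcomatoid-high 61, 2 without sarcomatoid-low 30 or 55, and 7 without sarcomatoid-low 23. The histone, ribosomal protein, proliferation, collagen, fibroblast and mesenchymal lists were called in all 44 such fits, though the collagen median ran from 0.20 to 0.89 and the mesenchymal from 0.17 to 0.57. The macrophage call was lost without sarcomatoid-high 21 or 53 or sarcomatoid-low 41 or 45 (adjusted p 0.0529 to 0.121), and the immediate early call without sarcomatoid-low 30, 51 or 55 (0.0766 to 0.127). The epithelial call was lost without sarcomatoid-high 21, 44, 58 or 61 or sarcomatoid-low 39, 41 or 45 (0.0516 to 0.215). The papillary call was lost without sarcomatoid-high 25, 31, 38, 58 or 61 or sarcomatoid-low 39 or 45 (0.0536 to 0.245). The HIF call was lost without sarcomatoid-high 25, 35, 47, 48, 52, 61, 63 or 64 or sarcomatoid-low 30, 40, 50, 51, 55 or 62 (0.0524 to 0.224). Lower calls were gained by the proximal tubule list in 14 such fits, checkpoints in 8, fatty acid oxidation in 7, T cells in 3 and endothelial genes in 1. Higher calls were gained by the adipocyte list in 3 fits, and by MYC targets, TGF-beta response and oxidative phosphorylation in 1 each. The cause was not tested.

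The list scores gave 0 calls under every alternative. Their sign turned for endothelial genes (0.0493) and interferon genes (-0.0952) with the median over members, for interferon genes with RLE (-0.0080) and for YAP and TAZ targets with a prior count of 0.5 (0.0086). Among 83 named genes, 9 changed sign, none with RLE or robust edgeR. With DESeq2 these were SOSTDC1 (0.64), SLC12A3 (-0.56) and ATP6V0A4 (1.61). With voom quality weights they were PCDH20 (0.30), SLC12A3 (-0.28), AQP3 (-0.15), IL6 (0.36), ATP6V0A4 (1.25), VIM (-0.017), CA9 (-1.37) and CD274 (-0.013); the cause was not tested. The variance explained was 1.92% to 2.03% over all alternatives.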

Other observations

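The length slope and proliferation covariates and the tests of depth and of a few tumours with high values were chosen after results were seen. The mesenchymal score of a sample can also follow its share of stroma, which was not separated from a mesenchymal state of tumour cells. The fibroblast and collagen lists were not among the lists related to it. Across the 44 tumours, 10 relations of the mesenchymal score with other lists were computed. The strongest was with fatty acid oxidation and peroxisome genes (Pearson r = -0.80, Spearman rho = -0.82, both with permutation p = 1e-05, the smallest the resamples can give, and adjusted p = 3e-05 and 5e-05). It was -0.77 without the 2 tumours farthest from the median mesenchymal score, -0.79 within sarcomatoid-high and -0.83 within sarcomatoid-low tumours. Those 2 were sarcomatoid-high 25 and sarcomatoid-low 41, the tumours with chromophobe and oncocytic scores of 10.2 and 10.1 log2 CPM. Each stayed in its class for the values by class. Epithelial genes gave r = -0.68 and rho = -0.66 (permutation p = 1e-05 for both, adjusted p = 3e-05 and 5e-05), -0.62 without those 2, -0.64 in sarcomatoid-high and -0.72 in sarcomatoid-low tumours. YAP and TAZ targets, which share 1 gene with the mesenchymal list, gave r = 0.68 (permutation p = 1e-05, adjusted p = 3e-05) and rho = 0.57 (permutation p = 0.0001, adjusted p = 0.00025), 0.59 without those 2, 0.66 and 0.73 by class. Proliferation gave r = 0.50 (permutation p = 0.00058, adjusted p = 0.00116) and rho = 0.58 (permutation p = 9e-05, adjusted p = 0.00025), 0.54 without those 2, 0.58 and 0.38 by class. The proximal tubule list gave r = -0.32 (permutation p = 0.0333, adjusted p = 0.0333) and rho = -0.45 (permutation p = 0.00267, adjusted p = 0.00534), -0.63 without those 2, -0.36 and -0.26 by class.

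Macrophage genes gave r = 0.55 (permutation p = 0.0001, adjusted p = 0.00025) and rho = 0.40 (permutation p = 0.0079, adjusted p = 0.0132), 0.36 without those 2, 0.51 and 0.59 by class. Checkpoints gave r = 0.47 (permutation p = 0.00147, adjusted p = 0.00245) and rho = 0.36 (permutation p = 0.0178, adjusted p = 0.0254), 0.36 without those 2, 0.68 and 0.34 by class. T and NK cell genes gave r = 0.42 (permutation p = 0.00468, adjusted p = 0.00585) and rho = 0.28 (permutation p = 0.0692, adjusted p = 0.0769), and r was 0.26 without those 2, 0.61 and 0.28 by class. Endothelial genes gave r = 0.33 (permutation p = 0.0288, adjusted p = 0.0320) and rho = 0.26 (permutation p = 0.0842, adjusted p = 0.0842), 0.31 without those 2, 0.27 and 0.40 by class. HIF targets, which share 1 gene, gave r = 0.44 (permutation p = 0.00302, adjusted p = 0.00431) and rho = 0.34 (permutation p = 0.0246, adjusted p = 0.0307), 0.38 without those 2. Their r was 0.20 in sarcomatoid-high and 0.75 in sarcomatoid-low tumours, a difference with a permutation p of 0.0293 and an adjusted p of 0.293 over the 10 relations, the other 9 having an adjusted p of 0.807.

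The tumour whose title named both classes had the lowest score of all in 6 lists. Its collagen score was 2.88 log2 CPM against a lowest of 4.18 in the other 44 tumours, its fibroblast score 1.71 against 2.29, its endothelial score 1.66 against 1.93 and its checkpoint score -0.27 against 0.03. Its B and plasma cell score was 0.16 against 0.27 and its immediate early score 4.59 against 5.17. Its papillary-associated score of 7.45 lay above 42 of the 44. Its profile was closest to sarcomatoid-low 39 (Spearman rho = 0.949 across genes) and sarcomatoid-low 45 (0.945), which correlated with each other at 0.942, while the next tumour reached 0.867 and the median over 990 pairs was 0.832. Genes are not independent replicates, so these values only describe the libraries.

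Histone and ribosomal protein lists, both of short transcripts, were called higher in sarcomatoid-high tumours with the preset correlation only (adjusted p = 0.663 and 0.786 with an estimated correlation). Total counts argue against a large depth difference (permutation p = 0.897). The 95% bootstrap interval of the difference was -1.89 to 1.76 M counts, and smaller differences within it stay possible. A difference in proliferation is a candidate explanation for the histones: with the proliferation score as a covariate their median log2 fold change was 0.2232, against 0.67 without it, with an adjusted p of 1.29e-07 at the preset correlation. Nephron list scores as covariates also lowered it, to 0.37, so the fall does not single out proliferation. The proliferation score itself had a permutation p of 0.225 between the classes. The shortest of 4 length groups of genes, up to 1059 bases, had a median log2 fold change of 0.04, and the longest -0.015. Against 0.67 for histones and 0.31 for ribosomal proteins, this argues against a length effect shared by all short transcripts as the main source. The length slope differed by -0.020 between the classes (permutation p = 0.226). With each library's length slope as a covariate the histone median was 0.5606, but the ribosomal median fell to 0.17. Length bias as a part of these differences stays open. The histone score difference has a standard error of 0.248, so the values do not decide on a smaller part. With the real split counted, a p as small as the real one came in 1 of the 80 splits for histones, in 13 for ribosomal proteins and in 14 for proliferation. For histones, the list picked as the smallest of 30, that 1 split was the real one itself. The smallest list p of each split is the fairer comparison for a list picked that way. Many other splits had a smallest adjusted p below the real 8.17e-12 (camera, preset correlation), such as 5.54e-27 and 6.59e-25. The histone p is therefore not shown to be rare.

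The genes with the smallest p may reflect a few tumours with high values. The 2 highest libraries held a median over 9 genes of 72.74% of the summed CPM of the class with the higher mean, from 30.7% for PPP1R3B to 98.7% for SOSTDC1. The excess of genes with the higher mean in sarcomatoid-high tumours in edgeR (650 against 268 unadjusted) could come from a wider spread there, though it was 231 against 209 with limma voom and turned to 289 against 352 with surrogate variables. The distance to the class centroid was larger by 3.66 units with a permutation p of 0.4528, which leaves that explanation open. The sarcomatoid class itself stays among the open explanations.

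Chance could not be excluded for the count of lists or of genes at an unadjusted p under 0.05. In 45 of 80 splits as many lists were called as the real 11, and the highest other split called 21. In 55 of 80 splits as many genes had an unadjusted p under 0.05 as the real 918, and the highest other split gave 2775. For genes past the adjusted threshold the real count is 0, which all 80 splits reach by construction, so the comparison says nothing about chance. Of the 79 other splits 57 called at least 1 such gene, with a median of 5 and up to 264. Splits that call so many genes may reflect a structure of the samples or a few tumours with high counts, and neither was tested for these splits.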
